A study of Mus musculus with 6 samples.

How the data were processed

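RNA from neurospheres was measured on 6 arrays of 1 Illumina mouse whole-genome beadchip (MouseWG-6). Neurospheres are floating clusters that neural stem and progenitor cells form in culture. Per the labels' protocols, cells from the subventricular zone, a germinal region of the adult brain, of mice aged 18 months were grown with EGF and FGF, and the spheres were taken at 14 days in vitro. The labels give the genotype, wild type (wt) or Wip1-transgenic (Wip1Tg), and whether spheres were primary or secondary. There was 1 wt primary array, 2 Wip1Tg primary arrays, 2 wt secondary arrays and 1 Wip1Tg secondary array. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples. For the 2 wt secondary arrays this spread may be technical, while the 2 Wip1Tg primary arrays differed in sex-linked transcripts, as given below. It is likewise not given in the labels whether the secondary spheres were grown from the primary ones measured here, which the sex-linked transcripts argue against for wt.

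The deposited non-normalized table holds, per the file headers, an intensity and a detection p-value for each of 45281 probes and each array. The values show the intensity to be linear and not background-subtracted, and the detection p-values to be multiples of 1 over 936. The deposited value table holds intensities that were quantile normalized by the authors, as the values show, since its sorted columns differ by at most 1.55 and each array has a rank correlation of 1 with its own non-normalized column. Its column medians were all 161.57. The scanner software and its version are not given in the sources used here.

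Background was corrected with limma's neqc, which fits a normal and exponential mixture with the background inferred from the detection p-values, adds an offset of 16, normalizes quantiles and takes log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept (18274 probes). Gene names came from the platform annotation, in which 34885 probes had 1 symbol, 18 had several and 10378 had none, and the reference table of assembly GRCm38.p6 was used only for names and for which genes share a chromosome. For a gene with several kept probes (3849 genes) the probe with the highest mean was used. This left 12755 features, of which 10167 were named genes and 2588 unnamed probes. Where the kept probes of a named gene differ in sign or size, the value belongs to the brightest probe only. Of 71 named genes with several kept probes, 23 had probes of both signs for genotype and 8 for passage.

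Linear models were fitted with limma 3.58.1 in R 4.3.3 and moderated with eBayes, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The model held genotype and passage as additive terms, leaving 3 residual degrees of freedom. A model with their interaction, leaving 2, gave the interaction and the genotype difference within each passage, where a lone array is assumed to vary like the other groups. Signs are Wip1Tg minus wt and secondary minus primary. Where a probe was not above background on any array of a group, the fold is given as "at least", computed from the mean of the brighter group and, per array of the dimmer group, the higher of its own value and the lowest value among probes above background.

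Before the data were examined, 21 gene lists were fixed. They cover p53 targets, p38 and damage signalling, Wnt ligands and receptors, Wnt inhibitors, β-catenin targets, Notch, proliferation, CDK inhibitors and senescence, the interferon response, immediate early and stress genes, hypoxia and glycolysis, and cholesterol synthesis. Cell type lists cover neural stem and progenitor cells, neuroblasts and neurons, astrocytes, the oligodendrocyte lineage, ependymal cilia, microglia and immune cells, endothelium, mural cells and fibroblasts, and choroid plexus. Of 567 list entries, 529 had a named probe. The 18 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, which has a test for a shift in one direction and a mixed test for change in either direction. Dkk3 was studied in the work behind these arrays, so its place on the Wnt inhibitor list is not independent evidence.

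The genes named were set by a rule fixed in advance. Always named were Ppm1d, Trp53, Mdm2, Cdkn1a, Dkk3, Axin2 and sex-linked genes used to check the labels. For each factor the rule took the 10 largest rises and 10 largest falls past the threshold with the same sign in each level of the other factor, leaving out unnamed probes and provisional names. Missing places were filled by smallest unadjusted p among genes with a log2 difference of at least 0.585, which are then said not to have passed. The rule also took 3 interaction genes of each sign, the largest past the threshold or, if none passed, those with the smallest unadjusted p. From each list it took the 4 members with the smallest unadjusted p. No probe was named Trp53 here, so it is not analysed here.

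The alternatives fixed in advance were no background correction, an offset of 50, cyclic loess, median scaling, the authors' value table, 3 other detection filters, the mean of a gene's probes, every probe on its own, the other factor left out, the averaged interaction model, trend and robust variance, array weights, no moderation, a threshold of 0.1, and leaving out each array. The interaction test of the lists was chosen after the data were seen.

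The fits were tested on simulated data made from the measured means and the eBayes-moderated spreads of the 12755 features, with independent normal noise and 200 changed genes. All 200 were changed at once by the same size, which eases the Benjamini-Hochberg cut, so the shares below do not hold for a gene changed alone. Moderated spreads vary less between genes than measured ones, so the shares may also be too high for the real arrays. There, Dkk3 at -1.30 and Nrgn at 1.18 did not pass for genotype, so a lack of calls does not exclude changes of this size. For genotype the simulation recovered 0% of genes changed by 0.585 log2, 90.5% of those changed by 1 and 100% of those changed by 2. For passage these were 0%, 88% and 100%. For the interaction, genes changed by 1 gave 0% and by 2 gave 94.5%, for genotype within primary spheres 1.5% and 99%, and within secondary spheres 0% and 97.5%. A simulated list of 20 independent genes moved by 0.5 log2 for genotype was called by camera at the preset correlation (adjusted p = 7.63e-21) and by fry (0.0184) and had an adjusted p = 0.0956 with an estimated correlation. For passage such a list was called by all 3, with camera at the preset correlation (adjusted p = 3.18e-30), with an estimated correlation (0.026) and with fry (0.0104). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value.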

Results

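Gene expression was measured in neurospheres of the adult mouse subventricular zone, from wt mice and from mice carrying a transgene for Wip1, the phosphatase encoded by Ppm1d that acts on p53, p38 and DNA damage kinases. Primary spheres gave 1 wt and 2 Wip1Tg arrays, and secondary spheres gave 2 wt and 1 Wip1Tg array. Median raw intensity lay between 150.88 and 168.44 per array, and 17623 to 18699 probes (38.92 to 41.3%) were above background. Replicates of one group correlated at 0.9901 to 0.9907 across the features tested, arrays of one passage but different genotype at 0.9802 to 0.9903, and arrays of different passage at 0.9405 to 0.9542. The first principal component held 72.3% of the variance and separated primary from secondary spheres.

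The labels describe the mice as matched for gender, and the transcripts of sex-linked genes were set against this. All 4 probes of Xist, which is transcribed from the inactive X chromosome, were above background on Wip1Tg primary 2 and on the 3 secondary arrays (mean log2 of the probes 8.71 to 8.98), and none was on wt primary 1 (4.64) or Wip1Tg primary 1 (4.70). Of the 2 probes of the Y-linked Kdm5d, 1 was above background on those same 2 arrays and on no other. Of the 4 probes of the Y-linked Uty, 1 was dimly above background on the 3 primary arrays and on wt secondary 1 (5.33 to 5.95). The Xist signal was therefore present on all secondary arrays and on 1 of the 3 primary arrays, and moved partly with passage. Xist and Kdm5d differed between Wip1Tg primary 1 and 2, which argues against the same donor animals for both. They also differed between wt primary 1 and the wt secondary arrays, which argues against growth of these secondary spheres from those primary ones. The arrays were thus not all alike in sex-linked transcripts, and the wt passage difference goes together with them.

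The first comparison asked how the Wip1 transgene changed expression in spheres of either passage. Dkk3, a secreted protein of the Dickkopf family of Wnt modulators, had the smallest p of all 12755 features. Its normalised log2 intensity was 10.41 in wt primary spheres and 9.02 and 9.09 in the 2 Wip1Tg primary arrays, then 7.14 and 7.29 in wt secondary and 5.97 in Wip1Tg secondary spheres. The Wip1Tg minus wt difference was -1.30 on the log2 scale (SE 0.117, 95% interval -1.58 to -1.02, n = 3 arrays per genotype), with -1.35 within primary and -1.24 within secondary spheres. With passage left out of the model the Dkk3 difference was -0.25 (adjusted p = 0.9871). That value mixes in the fall of Dkk3 with passage, since 2 Wip1Tg arrays but only 1 wt array were primary. Over all alternatives the Dkk3 difference ranged from -1.50 to -0.25, and as single arrays were left out from -1.35 to -1.22. With limma, Dkk3 did not pass over all features (adjusted p = 0.2173) and did pass adjusted over the list alone (adjusted p = 0.0002896 over the Wnt inhibitors), a list that is not independent evidence for a gene the study examined.

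Ppm1d itself was measured by 1 of its 4 probes, at log2 intensities of 9.29 in wt primary, 9.53 and 9.71 in Wip1Tg primary, 10.13 and 9.98 in wt secondary and 10.24 in Wip1Tg secondary spheres. Its genotype difference was 0.26 (SE 0.125, limma adjusted p = 0.5395), so the transgene was not visible as a change past the threshold. The construct is not given in the labels, and a probe outside the transgene would not report it. Mdm2, the ubiquitin ligase that restrains p53, differed by -0.14 (SE 0.13, limma adjusted p = 0.7453), and Cdkn1a, the p53-induced inhibitor of CDKs, by -0.41 (SE 0.264, limma adjusted p = 0.6233). Axin2, a feedback target of Wnt signalling, had a difference of -0.001 (SE 0.147, limma adjusted p = 0.9987).

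**Figure D1:**
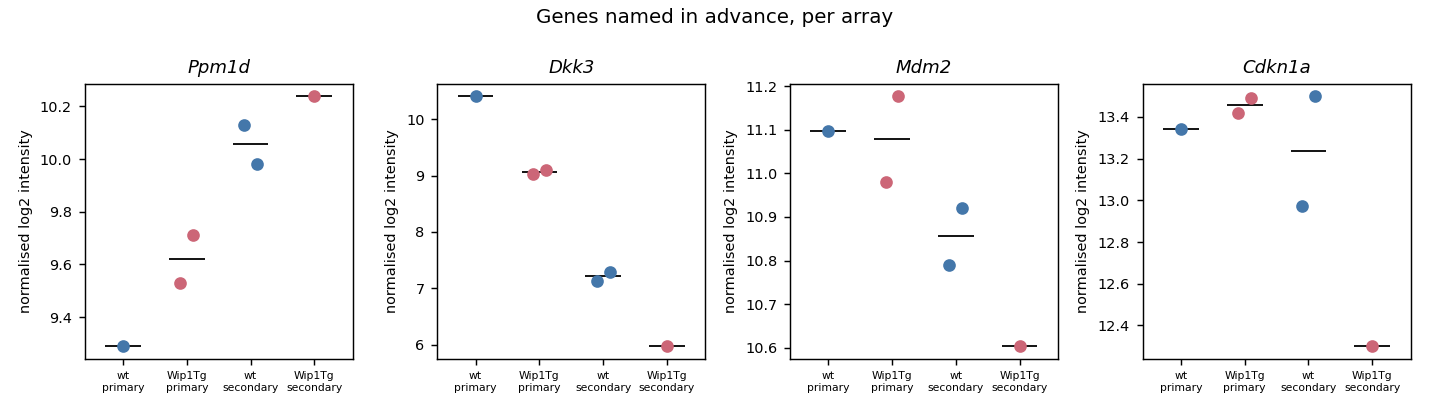
Normalised log2 intensity (vertical axis, a separate range per panel) of Ppm1d, Dkk3, Mdm2 and Cdkn1a by group (horizontal axis), with 1 point per array, blue for wt and red for Wip1Tg, and a line at the group mean. Dkk3 lay lower in Wip1Tg than in wt spheres within both passages, by 1.35 in primary and 1.24 in secondary spheres on the log2 scale.

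Over all features limma called 0 genes for genotype, with 1286 at an unadjusted p under 0.05 where chance gives 638. With trend and robust variance 1 gene, Dkk3, was called (adjusted p = 0.0318, range for Dkk3 over the alternatives 0.0318 to 0.9871). The genes that filled the places for higher expression in Wip1Tg spheres, none of which passed, were Nrgn (neurogranin, 1.18 log2, SE 0.181), Rnase1, Knstrn, Lrrcc1, Hecw2, Cox8b, Aunip, Ctse, Brwd3 and Clec2d, all at a limma adjusted p of 0.4345. Those for lower expression, after Dkk3, were Nat8, Csrp1, Flnc, Ttpa, Inf2, Per3, Gstm7, Cyp46a1 and Dnaic1, at the same adjusted p. Flnc, an actin crosslinker, differed by -1.08 (SE 0.172), Csrp1 by -1.06 (SE 0.165) and Per3, a clock gene, by -0.74 (SE 0.127). Hecw2 had probes of both signs.

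Cell cycle genes stood higher in Wip1Tg spheres as a group. All 30 measured members of the proliferation list had a positive difference (median 0.57), 0 passed over all genes and 20 passed adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, differed by 0.70 (SE 0.167), Mcm2 of the replicative helicase by 0.69 (SE 0.166), Cdc20 by 0.62 (SE 0.16) and Top2a by 0.92 (SE 0.237). The kept probes of Rrm2 ranged from 0.19 to 0.76 and those of Top2a from 0.31 to 0.92. Each gene named here was also higher on wt secondary 1 than on wt secondary 2 (Top2a 8.704 and 7.962, Rrm2 8.41 and 7.951). On Wip1Tg secondary 1 each was higher than on both (Top2a 9.537, Rrm2 8.872). Members of the list moved together, so the 30 positive differences and 20 passes are not separate pieces of evidence for genotype. Camera called the list higher (adjusted p = 1.834e-16), a call lost with an estimated correlation (adjusted p = 0.7945 with an estimated correlation of 0.696). All list calls for genotype and passage were lost in that test, also where the estimated correlation was small. The shift of the proliferation list was 0.43 within primary and 0.71 within secondary spheres.

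Interferon response genes and cholesterol synthesis genes were the other groups called higher. Of 24 interferon genes, 22 had a positive difference (median 0.43, camera adjusted p = 1.851e-05, adjusted p = 0.7945 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone, Stat2 at 0.58 (SE 0.152), Gbp3 at 0.70 (SE 0.187), Usp18 at 1.69 (SE 0.521) and H2-K1 at 0.43 (SE 0.15). Usp18 was at 0.47 without wt primary 1 and 2.89 without Wip1Tg secondary 1. Stat2, Gbp3, Usp18 and H2-K1 were also higher on Wip1Tg secondary 1 than on either wt secondary array, which their choice by smallest p favours. The median was 0.82 within primary and -0.14 within secondary spheres, and the call ended without wt primary 1 (-0.16) and on the 4 arrays with Xist signal (-0.12). Both of these alternatives take the genotype difference from secondary spheres alone, so they largely repeat the value within secondary spheres. Of 15 cholesterol genes, 14 were positive (median 0.19, camera adjusted p = 0.006059, adjusted p = 0.7945 with an estimated correlation) and 0 passed over all genes or adjusted over the list alone, with Lss at 0.52 (SE 0.209) and Mvk at 0.47 (SE 0.197). Its median was -0.032 under median scaling, where the median of all genes was -0.19 and camera still called the list higher (adjusted p = 0.008938). The cholesterol call ended without wt secondary 2, without Wip1Tg secondary 1 and with passage left out of the model.

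Oligodendrocyte, hypoxia and astrocyte genes were the groups called lower in Wip1Tg spheres. Of 21 oligodendrocyte lineage genes, 19 had a negative difference (median -0.44, camera adjusted p = 1.714e-06, adjusted p = 0.7945 with an estimated correlation), 0 passed over all genes and 3 passed adjusted over the list alone, the myelin genes Mag (-1.71, SE 0.41), Mbp (-1.76, SE 0.435) and Mal (-0.60, SE 0.157). The 3 kept probes of Mbp ranged from -1.76 to 0.037, and the reported one was at -1.16 without wt primary 1 and -2.36 without Wip1Tg secondary 1. All 17 hypoxia and glycolysis genes were negative (median -0.28, camera adjusted p = 1.442e-05, adjusted p = 0.7945 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone, P4ha1 at -0.90 (SE 0.259) and Pfkl at -0.79 (SE 0.276). The other kept probe of Pfkl gave -0.26. Of 22 astrocyte genes, 18 were negative (median -0.24, camera adjusted p = 0.006221, adjusted p = 0.7945 with an estimated correlation), with 0 passing either way, Gfap, the astrocyte intermediate filament, at -0.84 (SE 0.212) and Acsl6 at -0.35 (SE 0.118), whose probes had both signs. The hypoxia and astrocyte calls ended without Wip1Tg secondary 1, where the genotype difference comes from primary spheres alone. The astrocyte call also ended without Wip1Tg primary 2, and the hypoxia call with passage left out of the model.

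Lists of p53 and Wnt signalling were not called for genotype, and no member passed over all genes. The 35 p53 targets had a median of -0.074 (camera adjusted p = 0.3456, 12 positive and 23 negative values). Sesn1 was at -0.45 (SE 0.125), Gtse1 at 0.38 and Phlda3 at -0.48 (SE 0.157), and 0 passed adjusted over the list alone. Median scaling alone called the p53 list, as lower (median -0.295, adjusted p = 0.04353, range over the alternatives 0.04353 to 0.8787). The 17 p38 and damage genes had a median of 0.092 (adjusted p = 0.3456, 11 positive and 6 negative values). H2ax was at 0.50 (SE 0.156) and Mapkapk3, whose probes had both signs, at -0.42, with 0 passing adjusted over the list alone. This list was called higher only with passage left out of the model (adjusted p = 0.01352, range 0.01352 to 0.7285). The 21 Wnt ligands and receptors had a median of -0.043 (adjusted p = 0.9392), with Fzd3 at 0.39 (SE 0.147), whose probes had both signs, and 0 adjusted over the list alone. Of 17 Wnt inhibitors (median -0.003, adjusted p = 0.7628), 1 was higher, Cxxc4 at 0.59 (SE 0.142), and 1 lower, Dkk3, adjusted over the list alone. The 14 β-catenin targets had a median of -0.012, a mean of 0.017 and a camera direction of up (adjusted p = 0.7628), with Birc5 at 0.55 (SE 0.155) and Myc at 0.44 (SE 0.155), and 0 adjusted over the list alone.

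The remaining lists were not called for genotype either, with 0 members passing over all genes or adjusted over the list alone. Medians were 0.11 over 26 stem and progenitor genes (adjusted p = 0.7628, Hes5 at 0.71, SE 0.235), -0.055 over 18 neuronal genes (adjusted p = 0.3719, Rbfox3 at -0.67, SE 0.224) and 0.063 over 16 Notch genes (adjusted p = 0.7628, Nrarp at 0.63, SE 0.239). They were -0.006 over 17 CDK inhibitor and senescence genes (adjusted p = 0.8317, Lmnb1 at 0.57, SE 0.174) and -0.068 over 13 immediate early and stress genes (adjusted p = 0.4933, Ddit3 at -0.89, SE 0.426). The other kept probe of Lmnb1 gave 0.185. The 12 ependymal genes had a median of 0.008, a mean of -0.16 and a camera direction of down (adjusted p = 0.4933), with Tppp3 at -1.13 (SE 0.342), and were called only without Wip1Tg secondary 1 (adjusted p = 0.01108, range 0.01108 to 0.7859). The 5 mural and fibroblast genes had a median of 0.35 (adjusted p = 0.7628). With fry, 0 lists passed for genotype as a shift in one direction, and the Wnt inhibitors, the list that holds Dkk3, passed in its test of change in either direction (adjusted p = 0.01241).

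**Figure D2:**
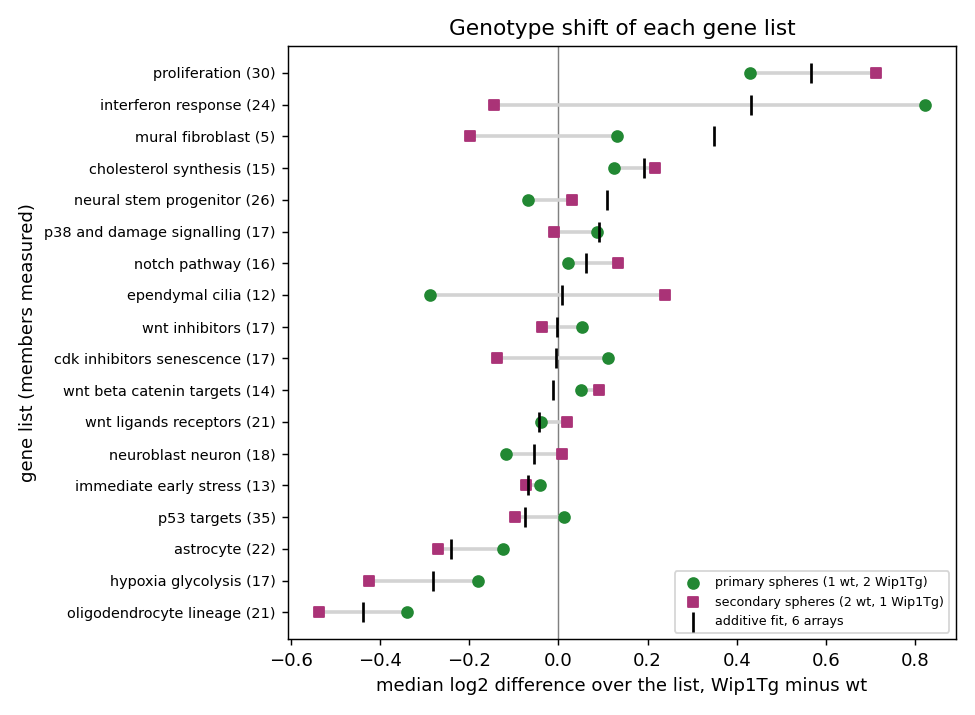
Median log2 difference, Wip1Tg minus wt (horizontal axis), over each of the 18 gene lists tested (vertical axis, with the number of members measured). Circles are the difference within primary spheres, squares that within secondary spheres and bars the additive fit over 6 arrays. The median of the proliferation genes lay above 0 in both passages (0.43 and 0.71) and that of the interferon genes in primary spheres alone (0.82 and -0.14).

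The second comparison asked what differed between secondary and primary spheres. Gjb6, the connexin 30 of astrocyte gap junctions, rose 30.2-fold (4.92 log2, SE 0.357, n = 3 arrays per passage, limma adjusted p = 0.000547), and Slc39a12, a zinc transporter, rose 15.0-fold (3.90 log2, SE 0.187, limma adjusted p = 0.0001954). Lcn2, an iron-siderophore binding protein of inflammation, fell at least 192-fold, and the neutrophil chemokine Cxcl1 fell at least 144-fold, since neither was above background on any secondary array (limma adjusted p = 0.0002317 and 0.0001212). Dkk3 fell 8.82-fold with passage (-3.14 log2, SE 0.117, limma adjusted p = 0.0001212) and Ppm1d rose 1.62-fold (0.69 log2, SE 0.125, limma adjusted p = 0.009851). The Ppm1d call ended in 5 of 22 alternatives, including those without wt primary 1 (0.62, adjusted p = 0.06452) and without Wip1Tg secondary 1 (0.76, adjusted p = 0.0509), over a range of 0.001618 to 0.1635. Without wt primary 1 the bound for Lcn2 was 112-fold.

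Of 12755 features 3583 (28.1%) passed for passage, 1826 higher and 1757 lower in secondary spheres, and 452 and 710 of them differed at least 2-fold. Among the calls, 192 were not above background on any secondary array and 63 on any primary array. The other largest rises were of the complement gene C2 (14.03-fold), Pdzph1 (12.4-fold), the cortisone reductase gene Hsd11b1 (10.99-fold), Gdpd3 (9.33-fold), the thyroid hormone transporter gene Slco1c1 (9.01-fold), Abhd3 (8.47-fold), Car10 (8.38-fold) and Sez6l (7.89-fold). Gjb6, Car10 and Sez6l were above background on 2 of the 3 primary arrays, so their folds are fitted values. The other largest falls were of Cxcl10 (77.0-fold as fitted, above background on 1 of 3 secondary arrays), Ptx3 (at least 41.9-fold), Ccl7 (at least 38.2-fold), the metalloprotease inhibitor gene Timp1 (39.4-fold), Thbs2 (at least 18.1-fold), Csrp1 (31.3-fold), Me1 (at least 19.7-fold) and Ccl2 (at least 18.2-fold). As single arrays were left out the log2 change of Gdpd3 went from 2.07 without wt primary 1, where its call ended (adjusted p = 0.1301), to 3.82 without Wip1Tg primary 2 and 4.39 without Wip1Tg secondary 1. That of Cxcl10 went from -7.37 without wt primary 1 to -5.12 without Wip1Tg secondary 1, and its second probe gave -2.05. Mdm2 (-0.36, SE 0.13, limma adjusted p = 0.08265), Cdkn1a (-0.63, SE 0.264, limma adjusted p = 0.1219) and Axin2 (0.015, SE 0.147, limma adjusted p = 0.9488) did not pass. The count was 1103 on the 4 arrays with Xist signal, 918 without eBayes moderation and 1384 without Wip1Tg secondary 1. Median scaling moved the split to 626 higher and 3235 lower.

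**Figure D3:**
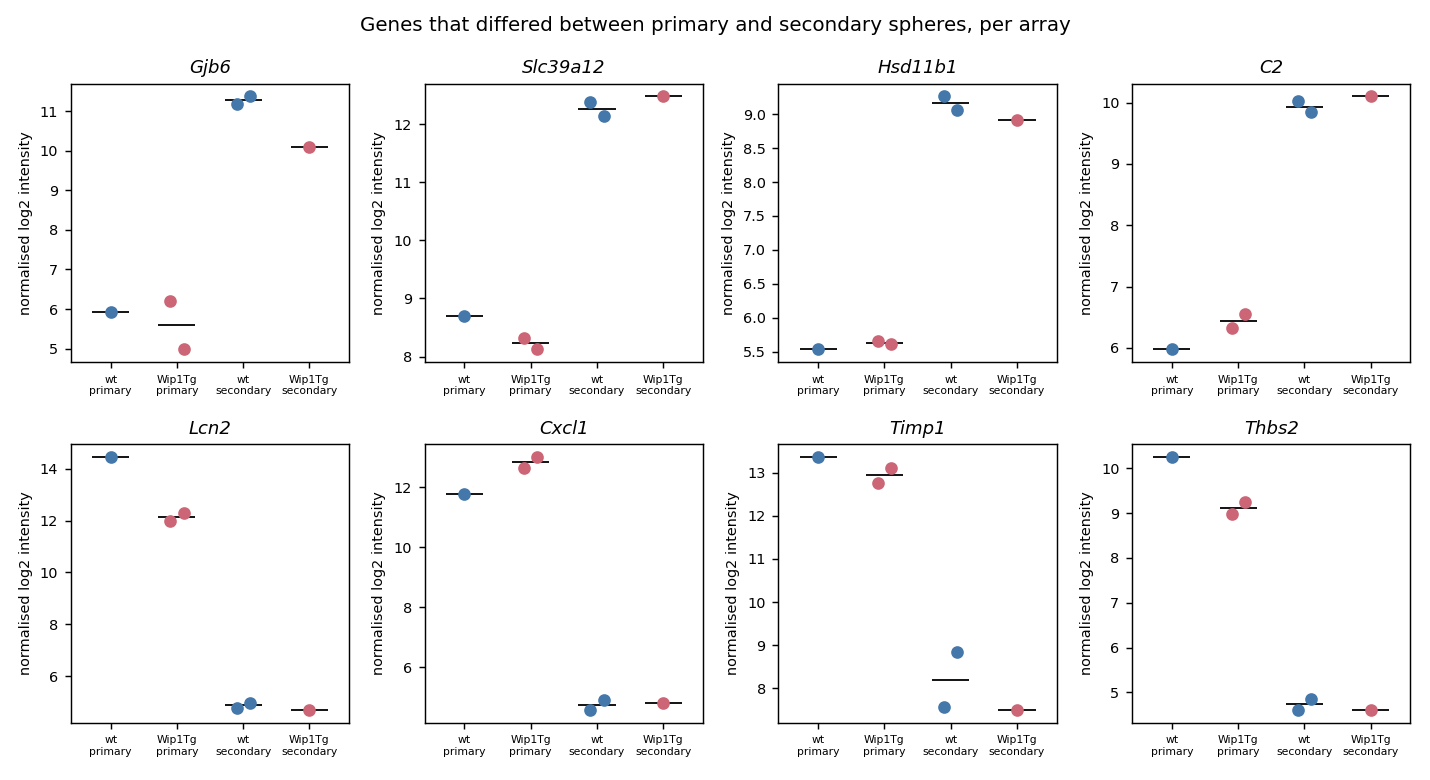
Normalised log2 intensity (vertical axis, a separate range per panel) of 4 genes higher and 4 genes lower in secondary spheres, by group (horizontal axis), with 1 point per array, blue for wt and red for Wip1Tg, and a line at the group mean. The primary and secondary arrays did not overlap for any of the 8 genes, and the Lcn2 and Cxcl1 probes were not above background on any secondary array.

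Astrocyte and Notch genes were the groups called higher in secondary spheres. Here and below, list members counted as having risen or fallen are those past the threshold over all genes. Of 22 astrocyte genes 14 rose and 1 fell, with 16 higher and 1 lower adjusted over the list alone (median 1.18, camera adjusted p = 9.969e-07, adjusted p = 0.4699 with an estimated correlation), among them Aldoc (2.11 log2, SE 0.161), the amino acid transporter gene Slc7a10 (at least 3.57-fold) and Acsl6 (1.38, SE 0.118). The gene of this list that fell was Gfap (-1.38, SE 0.212, limma adjusted p = 0.005743). Of 16 Notch genes 7 rose, 7 also adjusted over the list alone (median 0.39, camera adjusted p = 0.03695, adjusted p = 0.4699 with an estimated correlation), such as Hes5 (1.62, SE 0.235), Lfng (1.09, SE 0.116) and Dll1 (1.06, SE 0.169). The Notch call ended without wt primary 1, without Wip1Tg primary 2 and with the mean of the probes of a gene. The Dll1 call ended without Wip1Tg secondary 1 (0.83, adjusted p = 0.06678).

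Proliferation, interferon and senescence-associated genes were called lower in secondary spheres. Of 30 proliferation genes 20 fell, 24 adjusted over the list alone (median -0.74, camera adjusted p = 3.3e-09, adjusted p = 0.4699 with an estimated correlation), such as Cenpa (-1.22, SE 0.126), Cdc20 (-1.20, SE 0.16) and Prc1 (-1.07, SE 0.152). The other kept probe of Cenpa gave -0.12. Of 24 interferon genes 13 fell, 16 adjusted over the list alone (median -1.03, camera adjusted p = 9.969e-07, adjusted p = 0.4699 with an estimated correlation), such as Psmb8 (-2.17, SE 0.238), Gbp2 (-3.80, SE 0.423) and Usp18 (-3.93, SE 0.521, above background on 1 of 3 secondary arrays). Of 17 CDK inhibitor and senescence genes 8 fell, 9 adjusted over the list alone (median -0.63, camera adjusted p = 9.385e-05, adjusted p = 0.3508 with an estimated correlation), led by the secreted factors Cxcl1, Ccl2, Timp1 and Igfbp7 (-1.94, SE 0.173). Without wt primary 1 Gbp2 was at -4.62 and Usp18 at -5.07, and without Wip1Tg secondary 1 they were at -2.99 and -2.78.

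Lists of p53 targets, p38 and damage, hypoxia and glycolysis, immediate early and ependymal genes were also called lower in secondary spheres. Of 35 p53 targets 11 fell and 2 rose, 14 and 3 adjusted over the list alone (median -0.35, camera adjusted p = 0.001249, adjusted p = 0.4699 with an estimated correlation), such as Gadd45a (-1.82, SE 0.182), the death receptor gene Fas (-1.44, SE 0.146) and Ptp4a3 (-1.46, SE 0.134). Of 17 p38 and damage genes 7 fell, with 7 lower and 1 higher adjusted over the list alone (median -0.27, camera adjusted p = 0.01901, adjusted p = 0.4699 with an estimated correlation), such as Map2k3 (-0.92, SE 0.114) and Mapkapk3 (-1.18, SE 0.152). Of 17 hypoxia and glycolysis genes 7 fell, 9 adjusted over the list alone (median -0.68, camera adjusted p = 0.0002892, adjusted p = 0.4699 with an estimated correlation), such as Ndrg1 (-2.72, SE 0.24) and Ldha (-0.70, SE 0.147). Of 13 immediate early and stress genes 5 fell, 5 adjusted over the list alone (median -0.28, camera adjusted p = 0.03443, adjusted p = 0.4699 with an estimated correlation), such as Junb (-2.31, SE 0.265), Fos (-1.47, SE 0.2) and Hspb1 (-1.64, SE 0.166). Of 12 ependymal genes 6 fell, with 7 lower and 1 higher adjusted over the list alone (median -0.74, camera adjusted p = 0.04082, adjusted p = 0.4699 with an estimated correlation), such as Tppp3 (-2.29, SE 0.342) and Cfap126 (-1.63, SE 0.288, above background on 1 of 3 secondary arrays). The immediate early call ended in 6 alternatives (cyclic loess, the strict detection filter, the 4 arrays with Xist signal, and without wt primary 1, Wip1Tg primary 2 or Wip1Tg secondary 1). The ependymal call ended in 7 (cyclic loess, median scaling, the strict detection filter, genotype left out of the model, the 4 arrays with Xist signal, and without wt primary 1 or wt secondary 2). Without wt primary 1 the calls of Tppp3 (-1.94, adjusted p = 0.05444) and Cfap126 (-1.27, adjusted p = 0.08644) ended, and without Wip1Tg secondary 1 that of Ldha (-0.56, adjusted p = 0.1255).

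With fry 8 lists passed for passage as a shift in one direction, and 6 of these were among the 10 that camera called, the astrocyte, Notch, senescence, p53, p38 and immediate early lists. The other 2 were the Wnt inhibitors (fry adjusted p = 0.03894) and β-catenin targets (0.03024). The proliferation (fry adjusted p = 0.05041), interferon (0.07192), hypoxia (0.07192) and ependymal (0.07505) lists did not pass in this test. In the fry test of change in either direction all 18 lists passed for passage. This test does not compare a list with other genes, and 28.1% of all features passed for passage, so it singles out no list.

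The stem, neuronal and oligodendrocyte lists were not called for passage by camera and held genes past the threshold in both directions. The cholesterol list, with no gene past the threshold as lower (11 positive and 4 negative values), was not called either. Of 26 stem and progenitor genes 4 rose and 6 fell, 4 and 6 adjusted over the list alone (median 0.093, mean -0.019, camera direction down, adjusted p = 0.9484), with the Hedgehog genes Ptch1 (1.27, SE 0.126) and Gli2 (1.28, SE 0.135) higher and Tnc (-2.74, SE 0.159) lower. Of 18 neuronal genes 3 rose and 6 fell, 3 and 6 adjusted over the list alone (median -0.23, adjusted p = 0.2403), with Dcx of migrating neuroblasts higher (1.44, SE 0.163, above background on 1 of 3 primary arrays) and Nefm lower (-2.16, SE 0.185). Of 21 oligodendrocyte genes 6 rose and 5 fell, 6 and 6 adjusted over the list alone (median -0.037, mean 0.064, camera direction down, adjusted p = 0.8054), with Enpp6 higher (2.89, SE 0.335) and Trf lower (-3.75, SE 0.356). Of 15 cholesterol genes 3 rose, 2 adjusted over the list alone (median 0.27, adjusted p = 0.1335), with Dhcr7 at 1.33 (SE 0.188), and it was called only without the detection filter and without wt secondary 2 (adjusted p from 0.02236 to 0.289 over the alternatives). The Dcx change was 0.63 without wt secondary 1, and its call ended without Wip1Tg secondary 1 (adjusted p = 0.1457).

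Of 21 Wnt ligands and receptors 4 rose and 1 fell with passage, 4 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.3609), with Wnt5a higher (1.25, SE 0.176) and Wnt5b lower (-1.01, SE 0.144). Of 17 Wnt inhibitors 4 rose and 4 fell, 5 and 4 adjusted over the list alone (median -0.021, adjusted p = 0.7063), with Apcdd1 (-1.25, SE 0.171) and Shisa3 (-1.02, SE 0.152, above background on 1 of 3 secondary arrays) lower beside Dkk3. Of 14 β-catenin targets 3 rose and 6 fell, 4 and 6 adjusted over the list alone (median -0.003, adjusted p = 0.4649), with Cd44 lower (-2.24, SE 0.196) and Tcf7l2 higher (0.96, SE 0.153). The calls of Shisa3 (-0.90, adjusted p = 0.05379) and Tcf7l2 (0.82, adjusted p = 0.06678) ended without Wip1Tg secondary 1.

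Markers of other cell types were few, and for genotype 0 of them passed over all genes or adjusted over the list alone. Of 20 named microglia and immune genes 4 were measured, and of these Cd14 fell with passage (-1.53, SE 0.247), with 2 lower adjusted over the list alone. Of 18 named endothelial genes 3 were measured, and Flt1 (-1.96, SE 0.33) and Egfl7 (-1.02, SE 0.224) fell, 2 also adjusted over the list alone. Of 10 named choroid plexus genes 2 were measured, Sulf1 (-2.70, SE 0.305) and Otx2 (-1.10, SE 0.243, above background on 1 of 3 secondary arrays), and both fell, 2 also adjusted over the list alone. Of 5 mural and fibroblast genes 3 fell and 1 rose, 3 and 1 adjusted over the list alone (median -1.50, camera adjusted p = 0.1763), with Fbln1 at -1.64 (SE 0.192) and Fn1 at -1.50 (SE 0.333). Without Wip1Tg secondary 1 the calls of Cd14, Egfl7, Otx2 and Fn1 ended (adjusted p = 0.06807, 0.08656, 0.1642 and 0.08193), and without wt primary 1 that of Fn1 (0.1407). Flt1 was at -1.21 without wt primary 1 and -2.69 without Wip1Tg secondary 1.

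The third comparison asked whether the genotype difference itself differed between passages. Since none passed, the interaction genes named were the 3 of each sign with the smallest unadjusted p, so genes with larger but less precise interactions are not listed. Among those named, the largest interaction was at Rab26, a vesicle GTPase gene. Rab26 had a genotype difference of -5.84 in primary spheres and a fitted interaction of 5.61 (SE 0.492). It was above background on 1 of the 3 secondary arrays and Crym on none, so neither had a measured genotype difference in secondary spheres. Crym differed by -2.65 in primary spheres. The third positive interaction named was at Zfp385b (1.72, SE 0.214). Those named among negative interactions were H2-T10 (-2.62, SE 0.285), Gramd1a (-2.02, SE 0.234) and Zfp24 (-1.69, SE 0.249), with Gramd1a not above background on Wip1Tg secondary 1. None passed with limma (adjusted p = 0.4891 for all 6), 0 features passed in all and 1196 had an unadjusted p under 0.05, where chance gives 638. The primary-sphere values rest on 1 wt array, and 9 features passed under median scaling and 9 with trend and robust variance. Rab26 passed in 5 of 16 alternatives (adjusted p from 2.462e-06 to 0.6622), H2-T10 in 2 of 17 (0.008675 to 0.691) and Crym in 1 of 14 (0.005481 to 0.6622). The probes of H2-T10 had both signs for genotype.

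Within primary spheres limma called 0 genes for genotype (973 at an unadjusted p under 0.05, smallest adjusted p = 0.1143) and within secondary spheres 0 (1762, smallest adjusted p = 0.3179). With trend and robust variance these counts were 20 and 0. Across genes, the primary and secondary genotype differences, which share no array, correlated at r = 0.122 (Spearman's rho = 0.104), and 52.9% of genes had the same sign. Genes are not independent replicates.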

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

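The interaction test of the gene lists, and the tests of sex, probe, haplotype, genotype and other cells, were chosen only after the result was seen, while the counts over other splits of the arrays were planned. The genotype difference of 4 gene lists differed between primary and secondary spheres by camera at the preset correlation. Interferon genes had a median genotype difference of 0.82 in primary and -0.14 in secondary spheres (interaction adjusted p = 3.153e-13, negative for 24 of 24 genes). Proliferation genes had 0.43 and 0.71 (adjusted p = 0.00969), ependymal genes -0.29 and 0.24 (adjusted p = 0.0282) and hypoxia genes -0.18 and -0.42 (adjusted p = 0.04826). All 4 had an adjusted p = 0.8736 with an estimated correlation, and fry passed 0 lists for a shift in one direction and the ependymal list for change in either direction (adjusted p = 0.01196).

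Dkk3 was lower in Wip1Tg spheres of both passages, and it is among the features at which wt primary 1 (higher) and Wip1Tg secondary 1 (lower), the lone array of each passage, stood over 1 log2 from all 5 others. Sex of the donor animals is argued against, since Wip1Tg and wt arrays of one passage alike in Xist signal differed by -1.164 at the least, and so is a fault of the reported probe, since the second probe gave -1.249 or lower (SE 0.124, with Wip1Tg secondary 1, where it was not above background, set to the floor). Of the 9 splits of the arrays with the same layout, 1, the real one, gave a smallest p of 1.704e-05, against 0.0001333 in the next, but 9 splits are too few for a share under 0.05. An effect of the transgene on Dkk3 may underlie the difference and was not told apart from differences between single animals or cultures, as each passage holds 1 lone array.

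The wt primary array stood apart from the 5 others by over 1 log2 at features of which 32 were higher and 7 lower, against 3 higher and 34 lower on Wip1Tg secondary 1. The Wip1Tg genotype (median ratio of the secondary to the primary genotype difference 0.095, SE 0.072) and sex (median ratio of the distance of Wip1Tg primary 1, which also lacks Xist signal, to that of the other 4 arrays 0.57, SE 0.035) cannot be told apart from other causes, since choosing features over 1 log2 from every other array sets both ratios. Of 31 placed genes 7 lay on the chromosome of the H2 complex, including Rab26, Rhbdl1, H2-T10 and Zfp472 (one-sided Fisher p = 0.000675, 0.00405 adjusted over the 6 arrays), so an inherited haplotype different in the wt primary animals is a candidate explanation. That chromosome was picked after its genes were seen, and some features, such as Lcn2 and Csrp1 and, among the 7, Thbs2, were high in all primary spheres.

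The genes that differ between primary and secondary spheres were set against sex and other cells. Among the 4 arrays with Xist signal the fitted passage change is Wip1Tg secondary 1 minus Wip1Tg primary 2. There the called genes kept a median of 1.035 of the passage change (SE 0.005 over genes, which are not independent replicates). The called genes thus also differed between these arrays, which are alike in Xist signal. Both arrays also helped choose the genes, which favours a ratio near that value, so how much sex adds cannot be told. Other cells lost with passage stay open. Only 0.1 of the microglia and immune genes and 0.111 of the endothelial genes were above background on all 3 primary arrays. These were lower in secondary spheres (Cd14 -1.531, Egfl7 -1.019, Flt1 -1.959 and P2ry12 -0.885), though P2ry12 did not pass (limma adjusted p = 0.0526). Requiring signal on all primary arrays favours genes that fall with passage. The other measured members of these lists were not lower (Aif1 0.305, Csf1r 0.035 and Esam 0.326), and none of them passed. Passage, the design's own factor, may explain the difference, as may array, culture or animal differences that go with it, and these were not tested. The real split gave 3583 genes and the highest of the other splits 0, with 1 of 9 splits as large, and 9 splits are too few for a share under 0.05.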

How the results depend on the processing

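The alternative restricted to the 4 arrays with Xist signal was chosen after seeing the data, and all others before the data were examined. The genotype count was 0 under every alternative except eBayes with trend and robust variance, which called 1 gene, Dkk3 (adjusted p = 0.0318, over a range of 0.0318 to 0.9814 for the smallest adjusted p of all genes). The 3583 passage calls became 918 without eBayes moderation and 1103 on the 4 arrays with Xist signal, where 11773 features were tested. They ranged from 1384 to 2998 as single arrays were left out, with the lowest count without Wip1Tg secondary 1, then 1843 without wt primary 1, 2254 without Wip1Tg primary 1 and 2366 without wt secondary 1. Fewer samples leave fewer residual degrees of freedom in these fits. Where a group lost its lone array the additive model still estimated both effects. The genotype value then came from the other passage alone and the passage value from the other genotype alone. Such a genotype value repeats the difference within that passage and is no separate check. On the 4 arrays with Xist signal the genotype value likewise came from secondary spheres alone. Under median scaling the passage calls were 626 higher and 3235 lower (16.2% higher, against 51.0% as reported), and the median of all genes moved to -0.24 for passage, -0.19 for genotype and 0.18 for the interaction. The interaction count of 0 became 6 without background correction, 6 on the authors' value table, 9 under median scaling, 9 with trend and robust variance, and 1 each with an offset of 50, without the detection filter and with detection on 1 array. The primary-sphere genotype count of 0 became 17 without background correction, 18 on the authors' value table, 2 without the detection filter and 20 with trend and robust variance. List calls fell from 6 to 0 for genotype and from 10 to 0 for passage with an estimated correlation, and fry for a shift in one direction gave 0 for genotype and 8 for passage. The size of the correlation alone does not account for this loss. For passage the unadjusted camera p rose from 0.007391 to 0.08075 for the p38 and damage list (estimated correlation 0.015). For the senescence list (-0.014) it rose from 2.086e-05 to 0.01949. Otherwise the cause of these changes was not tested. No value exists for the interaction without wt primary 1 or Wip1Tg secondary 1, since it could not be fitted. No paired analysis was possible because the labels number only the 2 Wip1Tg primary and the 2 wt secondary arrays, which differ in both factors, so no numbers from the labels are shared within a passage or within a genotype. Only 38.9 to 41.3% of probes lay above background per array, which limits dim genes.

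Over the 101 gene values for genotype, 2124 of 2176 comparisons kept direction and side of the threshold, and over the 97 for passage, 1873 of 2046 did, with 144 losing the call. Over the 18 list medians, 231 of 287 comparisons for genotype and 250 of 287 for passage kept both.

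The log2 values below changed sign against those reported, as list medians or for single genes. With the other factor left out, each value mixes in part of that factor's effect, since genotype and passage were unbalanced over the arrays. Under median scaling the median of all genes itself moved to -0.19 for genotype and -0.24 for passage. Beyond this, the cause was not tested. With array weights, the genotype value was 0.038 for Axin2, 0.14 for P2ry12, 0.01 for Esam and -0.065 for Acta2, and the passage value was -0.024 for Axin2. On the authors' value table, the genotype value was 0.003 for Egfl7. Under cyclic loess, the genotype value was -0.028 for the ependymal list, and the passage value was -0.061 for Axin2. With detection required on 1 array, the genotype value was 0.51 for Aif1. Under the strict detection filter, the genotype value was 0.006 for the Wnt ligand and receptor list and 0.088 for the neuronal list, and the passage value was 0.29 for the Wnt inhibitor list, 0.017 for the neuronal list and 0.22 for the oligodendrocyte list. Under median scaling, the genotype value was -0.084 for Cd14, -0.011 for Egr1, -0.11 for the p38 and damage list, -0.092 for the stem cell list, -0.19 for the ependymal list, -0.13 for the Notch list and -0.032 for the cholesterol list, and the passage value was -0.33 for Axin2, -0.005 for Csf1r, -0.18 for the Wnt ligand and receptor list, -0.23 for the stem cell list and -0.043 for the cholesterol list. Without background correction, the genotype value was 0.005 for Egfl7. Without the detection filter, the genotype value was 0.51 for Aif1 and -0.006 for the ependymal list, and the passage value was 0.021 for the oligodendrocyte list. On the 4 arrays with Xist signal, the genotype value was 0.16 for Axin2, -0.32 for Cd14, 0.34 for P2ry12, 0.11 for Flt1, 0.023 for Esam, -0.93 for Thy1, 0.048 for Sulf1, -0.011 for the p38 and damage list, 0.098 for the Wnt ligand and receptor list, 0.064 for the Wnt inhibitor list, 0.086 for the β-catenin target list, 0.073 for the neuronal list, -0.20 for the mural and fibroblast list and -0.12 for the interferon list, and the passage value was -0.29 for Csf1r, 0.035 for the Wnt inhibitor list and 0.20 for the oligodendrocyte list. With the other factor left out, the genotype value was -0.10 for Rnase1, 0.59 for Csrp1, 0.14 for Gadd45a, 0.31 for Nefm, 0.08 for Trf, 0.27 for P2ry12, 0.024 for Flt1, 0.27 for Egfl7, 0.49 for Sulf1, 0.24 for Igfbp7, -0.023 for Dll1, 0.22 for Junb, 0.13 for Fos, 0.061 for the p53 target list, 0.10 for the β-catenin target list, -0.003 for the stem cell list, 0.024 for the neuronal list, 0.23 for the CDK inhibitor and senescence list, -0.043 for the Notch list and 0.089 for the immediate early and stress list, and the passage value was 0.009 for the Wnt inhibitor list and 0.23 for the oligodendrocyte list.

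As single arrays were left out, the genotype value ranged from -0.16 to 0.16 for Axin2, from -0.33 to 0.47 for Cd14, from -0.43 to 0.35 for P2ry12, from -1.36 to 0.11 for Flt1, from -0.23 to 0.024 for Esam, from -0.92 to 1.62 for Thy1, from -0.87 to 0.049 for Sulf1, from -0.011 to 0.091 for the p38 and damage list, from -0.066 to 0.033 for the Wnt ligand and receptor list, from -0.045 to 0.054 for the Wnt inhibitor list, from -0.038 to 0.091 for the β-catenin target list, from -0.063 to 0.11 for the stem cell list, from -0.20 to 0.041 for the neuronal list, from -0.20 to 0.30 for the mural and fibroblast list, from -0.16 to 0.83 for the interferon list, from -0.13 to 0.027 for Aif1, from -0.31 to 0.24 for the ependymal list, from -0.57 to 0.42 for Egfl7, from -0.23 to 1.02 for Acta2, from -0.24 to 0.11 for the CDK inhibitor and senescence list, from -0.93 to 0.12 for Cdkn1a, from -1 to 0.007 for Foxj1, from -0.20 to 0.075 for Igfbp2, from -0.039 to 0.45 for Egr1 and from -0.14 to 0.013 for the p53 target list. Likewise, the passage value ranged from -0.11 to 0.20 for Csf1r, from -0.24 to 0.22 for the oligodendrocyte list, from -0.032 to 0.11 for the Wnt inhibitor list, from -0.14 to 0.17 for Axin2, from -0.078 to 0.018 for the β-catenin target list and from -0.069 to 0.28 for the Wnt ligand and receptor list.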

Other observations

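The correlation over the choices of the lone arrays was tested after the result was seen, and the list splits were planned. Of the 9 splits of the arrays, 2 gave at least as many lists past the threshold for genotype as the real one, which gave 6 where the highest of the others gave 7. For passage 1 of 9 gave as many, with 10 in the real split and 9 in the highest other. For genes past the threshold for genotype all 9 splits gave 0. These splits are too few for a share under 0.05, and list calls at the preset correlation arose in every split.

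A genotype difference shared by both passages was a hypothesis for the correlation of 0.122 across genes between the primary and secondary genotype differences. Of the 9 choices of the lone array in each passage, 2 gave as high a correlation, the real one and another with 0.157, so the correlation may come from the arrays in either choice.

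Wip1Tg secondary 1 was lower than all 5 other arrays by over 1 log2 at 34 features, and without it the genotype calls of the hypoxia (median -0.181), astrocyte (-0.124) and cholesterol (0.124) lists ended and the ependymal list was called lower (-0.313). Without that array the genotype difference comes from primary spheres alone, so these medians largely repeat those within primary spheres.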
